A study of Homo sapiens with 6 samples.

How the data were processed

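Total RNA of MDA-MB-231 cells was amplified to biotin-labelled cRNA and hybridised to 6 whole-genome 3' expression arrays, 1 per sample, per the labels' protocols. The 3 control samples received a non-targeting siRNA and the 3 others a single siRNA against ING2, and no second ING2 siRNA is named in the labels. The authors deposited probe set intensity values on a linear scale for each array. RMA and R 2.12 are named in the submitters' processing notes. RMA gives log2 values as a rule, and the step that made linear values is not given in the sources used here. The deposited intensity values ran from 4.05 to 33803 and the 6 arrays had similar but not identical distributions. Background correction and filters are not given in the sources used here.

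The table held 54675 probe sets, of which 62 were control probe sets and were left out of the tests. Genes were named through a platform annotation of 2016, with symbols updated through gene identifiers to a RefSeq table of assembly GRCh38.p14, used for names only. That table held 19735 of the 19777 genes, which were counted by identifier, so 2 symbols (MIA2 and LINC00205) each stand for more than 1. Of the probe sets, 41091 named 1 gene, 1801 named several and 11721 were not listed with a gene. Probe sets naming several genes or none were left out of the gene tests and were tested on their own. For each gene, the probe set with the highest mean over all 6 arrays was used. More than 1 probe set was present for 10523 genes, and of 53 named genes with several, 31 had all probe sets on the same side of 0. The others were GRIA4, TEX11, DRP2, TAF13, RBBP4, MDM2, ECT2, CHEK1, LDLRAD4, TGFBR1, NEDD9, ADAM9, SDHD, NDUFS1, CASP8, BECN1, DICER1, TNRC6A, DCN, PDPN, LUM and LYZ.

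The log2 of each deposited value was taken with no pseudocount and no intensity filter. Groups were compared with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, ING2 siRNA minus control, with no covariate. Genes with a Benjamini-Hochberg adjusted p under 0.05 over all 19777 genes were called higher or lower. Single values per array were compared with an exact two-sided permutation test, which cannot go below p = 0.1 with 3 against 3 arrays.

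The 27 gene lists were tested with camera at a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the lists. They cover the ING family, the SIN3-HDAC complex, p53 targets, DNA replication, mitosis, replication-dependent histones, double-strand break repair, mesenchymal and epithelial genes, TGF-beta and SMAD targets, matrix proteases and their inhibitors, metastasis genes of the line, NF-kB targets, the interferon response, antigen presentation, cholesterol synthesis, the unfolded protein response, hypoxia and glycolysis, the respiratory chain, cytosolic ribosomal proteins, apoptosis, autophagy and lysosome, immediate early genes, the RNA interference machinery, and markers of luminal breast cells, fibroblasts and blood cells. Camera compares the mean test statistic of a list with that of all other genes, and does not compare medians. A list with a median above 0, or above the median log2 change of 0.06 over all genes, can therefore have a lower direction. Each list's median was also set against 10000 random lists of the same size, matched on mean intensity in 50 bins.

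The groups, tests, threshold, gene lists and the rule for named genes were fixed before the data were examined. The rule names ING2, then the 12 largest rises and 12 largest falls among genes past the threshold whose groups did not overlap, leaving out identifiers without a gene name. In each list it names the members past the threshold, up to 3 rises and 3 falls, and in a list with none the 2 with the smallest p. Other ING genes and SIN3-HDAC members may be named under it. HLA-B, HLA-C and a few mitosis genes were named after their values were seen.

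The method was tested on simulated data for this comparison with 19777 genes. Of 100 genes changed by 0.5 on the log2 scale 49% were recovered, and of 100 changed by 1, 95%, while 2 unchanged genes were called. Simulated genes were independent, with no intensity trend between the arrays, so the simulation does not measure false calls on the real arrays. Alternatives were median centring of each array, quantile normalization, leaving out dim probe sets, the mean of a gene's probe sets or the one with the largest interquartile range, an intensity trend with robust eBayes, array weights, the replicate number as a block, leaving out each array, each probe set on its own, stricter thresholds, an ordinary two-sample test, an estimated correlation in camera, and fry. Cyclic loess with 3 iterations and the ING family list without ING2 were added after the data were seen. Matches of the siRNA seed to transcripts were not analysed here.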

Results

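Messenger RNA was measured on 6 one-colour oligonucleotide arrays, 3 from MDA-MB-231 cells given a non-targeting control siRNA and 3 from cells given an siRNA against ING2. MDA-MB-231 is an established human breast cancer line with mesenchymal features that lacks the estrogen receptor. ING2 encodes a PHD finger protein that binds trimethylated lysine of histone H3 and is a subunit of a SIN3 histone deacetylase complex. The labels place RNA collection at 4 days after transfection in one field and at 3 days in another. Median intensity per array lay between 75.7 and 81.5, and the number of arrays limits the precision of every value. The labels do not say that replicates were separate cultures, so p-values measure the spread between these samples, which may be technical. Pearson correlations across genes were 0.9964 to 0.9981 between control arrays, 0.9968 to 0.9972 between ING2 siRNA arrays and 0.9923 to 0.9969 between the groups, and genes are not independent replicates. No pair of arrays held the same values. The first principal component, with 58.2% of the variance, separated the control arrays (-21.6 to -6.41) from the ING2 siRNA arrays (5.52 to 21.8). It ordered the 6 arrays as their median intensity did, which also did not overlap between the groups. Control replicate 1 correlated better with ING2 siRNA replicate 2 (0.9969) than with control replicates 2 (0.9964) and 3 (0.9967).

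The comparison asks which transcripts differ when ING2 is depleted in these cells. ING2 mRNA fell to 12.5% of the control level. Its main probe set, 205981_s_at, read 1400, 1349 and 1324 intensity units in the controls and 163, 188 and 161 units after ING2 siRNA, a log2 change of -2.997 (SE 0.09, n = 3 per group, limma adjusted p = 1.85e-07 by Benjamini-Hochberg). The groups did not overlap, and the exact two-sided permutation test gave p = 0.1, the smallest that 3 against 3 arrays allow. A dimmer probe set of the gene, 213544_at, went from a geometric mean of 91.3 to 33.4 units, 36.5% of control.

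Among the other ING genes, ING3, a subunit of the NuA4 histone acetyltransferase complex, fell by 0.40 on the log2 scale (SE 0.10, limma adjusted p = 0.0455), with adjusted p = 0.0513 after quantile normalization. Log2 changes of ING5 (-0.19), ING4 (-0.02) and ING1 (0.25) did not pass the threshold in the deposited values. ING1 passed as higher after quantile normalization (0.36, limma adjusted p = 0.0355) and after cyclic loess (0.33, limma adjusted p = 0.0454). ING4 had a value above 0 after quantile normalization (0.08) and cyclic loess (0.04). Of the 5 family members, 0 rose and 2 fell (1 and 2 adjusted over the list alone), with a median of -0.19. The family was lower by camera (Benjamini-Hochberg adjusted p = 0.0174), with adjusted p = 0.56 with an estimated correlation, 0.104 after cyclic loess, 0.0657 with the probe set of largest interquartile range and 0.442 without ING2 itself. In the SIN3 deacetylase complex, 1 of 18 measured members changed (2 higher and 5 lower adjusted over the list alone). The histone-binding subunit RBBP4 fell by 0.51 (SE 0.09, limma adjusted p = 0.0242). Values for other subunits were -0.33 for SAP30, -0.33 for MORF4L1, -0.32 for HDAC2, -0.04 for HDAC1, 0.20 for SIN3A, 0.31 for SIN3B and 0.32 for SAP130, none past the threshold in the deposited values. SAP130 passed as higher after quantile normalization (limma adjusted p = 0.0326) and cyclic loess (0.0411). SIN3B passed as higher after quantile normalization (limma adjusted p = 0.0382) but not after cyclic loess (0.0523). HDAC1 was above 0 after quantile normalization (0.09). The complex as a list had a median of -0.11 and did not pass (camera adjusted p = 0.0661), but was lower without control replicate 1 (0.0442) or ING2 siRNA replicate 2 (0.0340), with the mean of all probe sets (0.0315), the probe set of largest interquartile range (0.0426) and an intensity trend with robust eBayes (0.0492). Its adjusted p was 0.161 without control replicate 2 and 0.697 after cyclic loess.

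**Figure D1:**
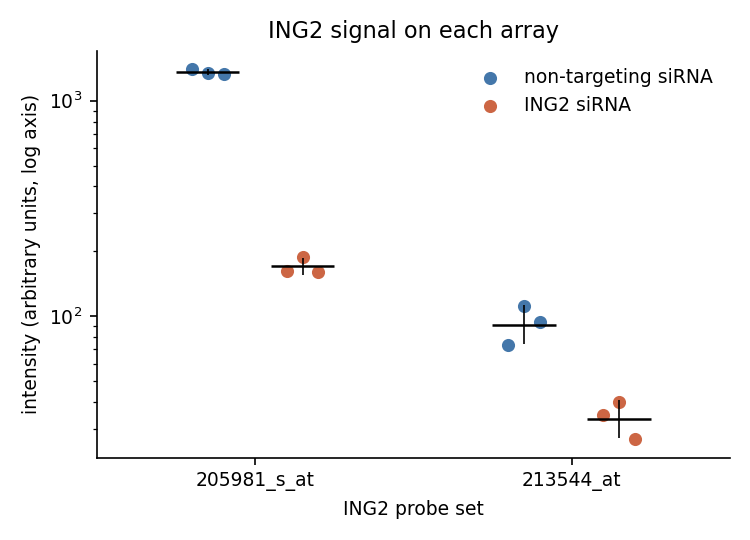
Intensity in arbitrary units (y axis, log scale) of the 2 ING2 probe sets (x axis) on each array, coloured by group, with a bar at the geometric mean and a line for the SD of the log2 values (n = 3). Every array given ING2 siRNA lies below every control array for both probe sets.

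Besides ING2, the largest falls were in TMA16, a ribosome-associated protein (log2 -1.18, SE 0.26, 2.27-fold), FAM76B (-1.13, SE 0.30), the small proteasome subunit SEM1 (-1.10, SE 0.10, limma adjusted p = 0.00402) and ACSL4 (-1.04, SE 0.25), which activates arachidonate and related fatty acids. They were followed by the monocarboxylate carrier SLC16A4 (-0.95), the epithelial adhesion molecule EPCAM (-0.95, SE 0.12), the actin-related chromatin subunit ACTL6A (-0.95), the TFIID subunit TAF13 (-0.94), the mitochondrial fusion factor MIGA1 (-0.94), NXPE3 (-0.93), EDEM3 (-0.93), which trims mannose from misfolded glycoproteins, and RNFT1 (-0.93). The largest rises were smaller, from 0.58 to 0.67. They were VIPR1, a receptor for vasoactive intestinal peptide (0.67, SE 0.10, limma adjusted p = 0.0176), the glutamate receptor subunit GRIA4 (0.61), CADM1-AS1 (0.60), PRSS2 (0.60), TEX11 (0.60), DRP2 (0.60), the hepcidin regulator TMPRSS6 (0.59), NALF1 (0.59), KASH5 (0.58), SLITRK1 (0.58), SPATA42 (0.58) and the focal adhesion protein ZYX (0.58). PRSS2 is uncertain, since trypsinogen genes are close copies. Of the 12 rises, 8 were in genes below the median intensity, against 2 of the 12 falls. The dimmest rise was that of SLITRK1, at percentile 7.04 of genes by intensity (mean log2 intensity 3.59 in controls and 4.17 after ING2 siRNA). Dim genes as a class had median log2 changes of up to 0.15. After cyclic loess, TEX11 (adjusted p = 0.0654), SPATA42 (0.0590) and FAM76B (0.0518) no longer passed. Over the 6 fits that each left out 1 array, FAM76B ranged from -1.43 to -0.71 and passed in 1. In the same fits TMA16 ranged from -1.49 to -0.94 and passed in 2. Other probe sets of GRIA4, TEX11, DRP2 and TAF13 had values near 0 or of the other sign, the lowest being -0.06 for DRP2 and the highest for TAF13 being 0.02.

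In all, 1640 of 19777 genes passed the threshold in limma, 716 higher and 924 lower (adjusted p from 0.01 to 0.05 for 1638 of them). Of those past it, 8 were higher and 247 lower by at least 1.5-fold, and 0 higher and 5 lower by at least 2-fold. Groups did not overlap in 36.5% of all genes, against 10% by chance. Genes that rose were dim and genes that fell were bright: 72.9% of the rises and 11.7% of the falls lay below the median intensity. With genes in 10 bins of equal size by intensity, the median log2 change went from 0.15 in dim bins to -0.09 in the brightest. In the same arrays the interquartile range of log2 intensity was 3.35 ± 0.03 in controls and 3.19 ± 0.08 after ING2 siRNA (SD, n = 3, exact permutation p = 0.1). The GAPDH control probe sets, a measure of RNA integrity, read 0.205 ± 0.015 log2 units higher at the 3' than at the 5' end in controls and 0.316 ± 0.042 after ING2 siRNA (SD, n = 3, exact permutation p = 0.1), with no overlap between the groups. For ACTB the values were 0.490 ± 0.110 and 0.541 ± 0.096 (exact permutation p = 0.6). After cyclic loess, 266 of the rises and 598 of the falls remained. The count depended on single arrays: 2 genes passed without control replicate 2, 3 without control replicate 3, 3 without ING2 siRNA replicate 1 and 2 without ING2 siRNA replicate 3, against 2613 without control replicate 1 and 2577 without ING2 siRNA replicate 2. ING2 and SEM1 passed in each of these 6 fits. All 1640 genes kept their direction in them, but groups did not overlap in 1635 of them. Leaving out 1 array cannot turn the direction of such a gene, so this is no sign of stability.

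**Figure D2:**
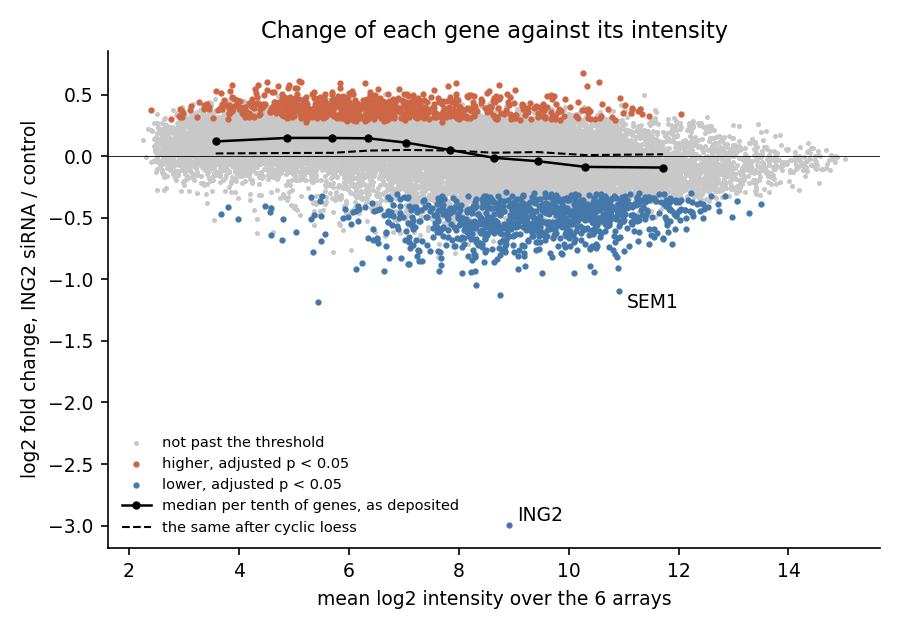
Log2 change after ING2 siRNA (y axis) against mean log2 intensity (x axis) for each gene, coloured where it passed the threshold, with lines for the median of each of 10 bins as deposited (solid) and after cyclic loess (dashed). The solid line goes from 0.15 in dim bins to -0.09 in the brightest.

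Genes of mitosis were lower as a group by camera (Benjamini-Hochberg adjusted p = 6.88e-12), but not with an estimated correlation (adjusted p = 0.56). Of 48 measured, 17 fell and 1 rose (26 and 1 adjusted over the list alone), 41 had a value below 0 and the median was -0.26. KIF23, a kinesin of the central spindle, fell by 0.78 (SE 0.13, limma adjusted p = 0.0193), the spindle checkpoint protein MAD2L1 fell by 0.75 (SE 0.15) and the cytokinesis factor ECT2 fell by 0.67 (SE 0.17). Another ECT2 probe set had a value of 0.27 that did not pass. The phosphatase gene CDC25B rose by 0.35 (SE 0.09). Named after their values were seen, the cyclin genes CCNA2 (-0.62) and CCNB1 (-0.43) and the kinase gene CDK1 (-0.50) also fell, and the values for MKI67 (-0.07), PLK1 (0.14) and FOXM1 (0.21) did not pass. Relative to the control mean, the mean over the list was -0.28 ± 0.06 after ING2 siRNA, against 0 ± 0.10 in controls (SD, n = 3, exact permutation p = 0.1). After cyclic loess the list had a camera adjusted p of 5.48e-06 and 11 members fell, and ECT2 (adjusted p = 0.0547) and CDK1 (0.0622) no longer passed. Without control replicate 2 or 3, or ING2 siRNA replicate 1 or 3, 0 members passed, while the list median stayed between -0.28 and -0.23 over the 6 fits.

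Genes of DNA replication showed 0 rises and 4 falls among 43 members (1 and 7 adjusted over the list alone), with a median of -0.10 that was 0.03 after quantile normalization. The sliding clamp PCNA fell by 0.47, the polymerase subunit POLE2 fell by 0.38 and the histone mRNA-binding protein SLBP fell by 0.33, none of them past the threshold after cyclic loess (adjusted p = 0.0881, 0.0501 and 0.0969 in limma). The list was lower by camera (adjusted p = 0.0146), with adjusted p = 0.58 with an estimated correlation, 0.56 after cyclic loess and 0.0623 without ING2 siRNA replicate 1. Among 16 replication-dependent histone genes, which are near-identical copies and therefore uncertain, H2BC9 fell by 0.47 and 15 did not pass (0 higher and 1 lower adjusted over the list alone, median -0.02, camera adjusted p = 0.338). In double-strand break repair 0 of 30 genes rose and 3 fell, also when adjusted over the list alone. These were the checkpoint kinase CHEK1 (-0.58, SE 0.09), the end-joining factor XRCC4 (-0.57, SE 0.11) and RAD51AP1 (-0.55, SE 0.14, limma adjusted p = 0.0543 after cyclic loess). The repair list had a median of -0.14 and was lower by camera (adjusted p = 0.00276), with adjusted p = 0.58 with an estimated correlation and 0.104 after cyclic loess.

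**Figure D3:**
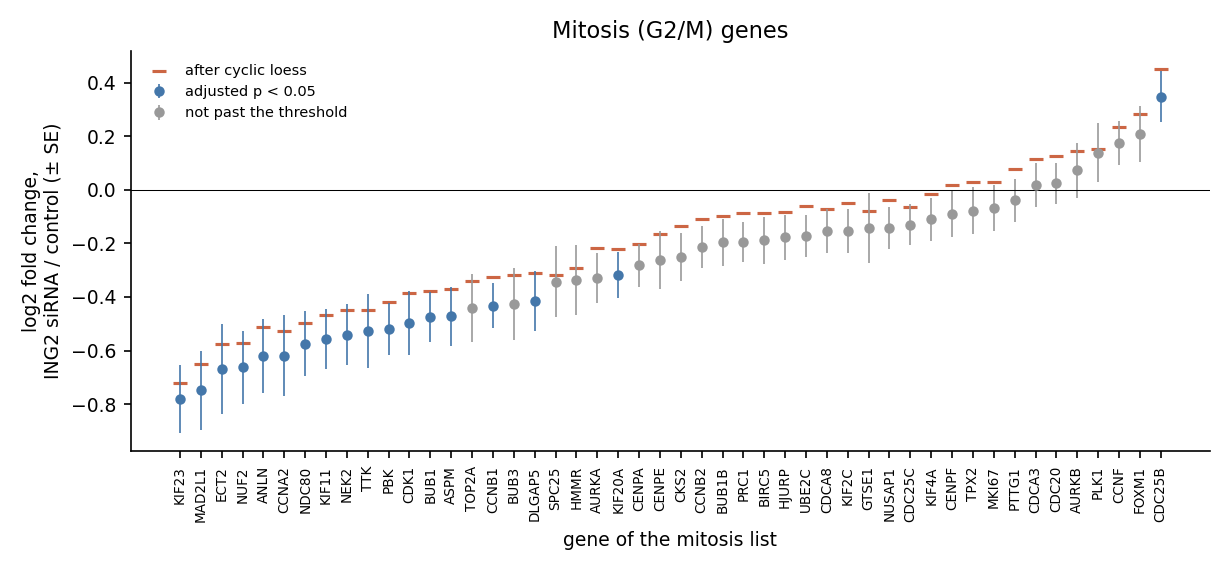
Log2 change after ING2 siRNA (y axis, points with SE) of each of the 48 genes of the mitosis list (x axis), coloured where past the threshold, with a dash for the value after cyclic loess. In the deposited values 41 of the genes lie below 0.

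Targets of p53 included 0 rises and 2 falls among 25 genes (1 and 2 adjusted over the list alone), with a median of -0.12. PMAIP1, which encodes the death-promoting protein NOXA, fell by 0.62 (SE 0.08, limma adjusted p = 0.0134), and the p53 ubiquitin ligase gene MDM2 fell by 0.58 (SE 0.15). MDM2 had adjusted p = 0.0502 after cyclic loess, and 4 of its 10 probe sets had a value below 0. The p53 list was lower by camera (adjusted p = 0.0132), with adjusted p = 0.56 with an estimated correlation and 0.291 after cyclic loess. Of 35 apoptosis regulators, 1 rose and 3 fell (1 and 4 adjusted over the list alone): BMF, a BH3-only protein, rose by 0.39, and PMAIP1, the caspase inhibitor XIAP (-0.60) and the initiator caspase CASP8 (-0.44) fell. XIAP (limma adjusted p = 0.0598) and CASP8 (0.0517) did not pass after cyclic loess, and the list did not pass as a whole (median -0.04, camera adjusted p = 0.0764), but was lower with the mean of all probe sets (0.00518), the probe set of largest interquartile range (0.0137) and without ING2 siRNA replicate 2 (0.0478). Its adjusted p was 0.196 without ING2 siRNA replicate 3 and 0.921 after cyclic loess. In autophagy and lysosome genes 1 of 32 rose and 3 fell (1 and 5 adjusted over the list alone). MAP1LC3A rose by 0.35, and ATG12 (-0.57), BECN1 (-0.51) and ULK2 (-0.49), which act in autophagosome formation, fell. Of 3 BECN1 probe sets, 2 fell past the threshold and the other had a value of 0.30 that did not pass. The median of that list was 0.07, at percentile 99.9 of lists matched on intensity, its mean was -0.03, and the camera direction was lower (adjusted p = 0.351). The direction was higher after quantile normalization (median 0.17, adjusted p = 0.509) and cyclic loess (median 0.13, adjusted p = 0.410).

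In antigen presentation, the MHC class II chain gene HLA-DRA fell by 0.79 (SE 0.12, limma adjusted p = 0.0170), the class II chain gene HLA-DPA1 fell by 0.56 (SE 0.10) and HLA-DMB, which loads class II molecules, fell by 0.48 (SE 0.10), each past the threshold after cyclic loess too. The class I genes HLA-B and HLA-C, close copies of each other and named after their values were seen, both had a value of 0.04. Of 21 antigen presentation genes, 0 rose and 3 fell (0 and 6 adjusted over the list alone), with a median of -0.07 that was 0.01 after cyclic loess and 0.04 after quantile normalization. The list was lower by camera (adjusted p = 0.0174), with adjusted p = 0.56 with an estimated correlation, 0.595 after cyclic loess, 0.0595 without control replicate 1 and 0.294 with the probe set of largest interquartile range. Among 40 interferon response genes 1 rose and 2 fell (1 and 3 adjusted over the list alone), with a median of -0.11. TRIM22, an antiviral ubiquitin ligase, fell by 0.59 (SE 0.11), IFIT1, which binds viral RNA, fell by 0.50 (SE 0.10), and IFNL1 rose by 0.34 (0.22 with limma adjusted p = 0.122 after cyclic loess). This list was lower by camera (adjusted p = 0.00151), with adjusted p = 0.56 with an estimated correlation and 0.0842 after cyclic loess. Of 30 NF-kB target genes, the chemokine gene CCL2 fell by 0.44 (SE 0.11) and none rose (0 and 0 adjusted over the list alone). Their median was 0.04 and the camera direction lower (adjusted p = 0.934).

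Mesenchymal genes included 1 rise and 1 fall among 32 (3 and 1 adjusted over the list alone, median 0.08, camera adjusted p = 0.338). The fibronectin receptor subunit ITGA5 rose by 0.50 (SE 0.10), and the transcription factor gene SNAI2 fell by 0.36, with limma adjusted p = 0.0809 after cyclic loess. In 30 epithelial genes EPCAM and the tight junction gene OCLN (-0.44) fell and none rose (0 and 2 adjusted over the list alone), with a median of 0.04 and a lower camera direction (adjusted p = 0.767). TGF-beta and SMAD targets had 2 rises and 3 falls among 28 (4 and 4 adjusted over the list alone, median -0.06, camera adjusted p = 0.200). LDLRAD4, which restrains SMAD signalling, rose by 0.51 and the collagen gene COL4A2 rose by 0.40, while the receptor gene TGFBR1 fell by 0.70 (SE 0.10, limma adjusted p = 0.0170), ID3 fell by 0.57 and the adhesion scaffold gene NEDD9 fell by 0.51. For NEDD9, 3 of 5 probe sets had a value below 0, and the highest value was 0.26. NEDD9 was the only gene past the threshold of 24 genes tied to metastasis of this line (0 higher and 1 lower adjusted over the list alone, median -0.03, camera adjusted p = 0.478). Of 32 matrix proteases and inhibitors 2 rose and 2 fell (5 and 6 adjusted over the list alone, median 0.08, camera adjusted p = 0.739). MMP10 (0.48) and MMP13 (0.46) rose from low intensity, and ADAM9 (-0.46) and CTSV (-0.37) fell. MMP13, ADAM9 and CTSV did not pass after cyclic loess (limma adjusted p = 0.0622, 0.0812 and 0.0540). Among 30 immediate early genes 3 rose and 1 fell (5 and 3 adjusted over the list alone, median 0.07, camera adjusted p = 0.812). The AP-1 gene FOSL1 rose by 0.57 (SE 0.12), IER2 rose by 0.35, and of the receptor signalling inhibitors SPRY4 rose by 0.32 and SPRY2 fell by 0.34 (-0.25 with limma adjusted p = 0.0833 after cyclic loess).

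Cholesterol synthesis genes had 0 rises and 3 falls among 19 (0 and 5 adjusted over the list alone, median -0.17). INSIG1, which retains the sterol sensor in the endoplasmic reticulum, fell by 0.66 (SE 0.09, limma adjusted p = 0.0167), IDI1 fell by 0.50 and MSMO1 fell by 0.37, with adjusted p = 0.0797 for MSMO1 after cyclic loess and 0.0535 for IDI1 after quantile normalization. The list was lower by camera (adjusted p = 0.00393), with adjusted p = 0.56 with an estimated correlation and 0.291 after cyclic loess. Respiratory chain genes had 0 rises and 4 falls among 34 (0 and 5 adjusted over the list alone, median -0.13). SDHD fell by 0.55 (SE 0.10), though its other probe set had a value of 0.30 that did not pass. UQCRB (-0.36) and NDUFS1 (-0.35) also fell, with values of -0.25 and -0.26 after cyclic loess (limma adjusted p = 0.0940 and 0.0964). Their list was lower by camera (adjusted p = 6.03e-05), with adjusted p = 0.58 with an estimated correlation and 0.358 after cyclic loess. Of 36 cytosolic ribosomal protein genes, RPS25 fell by 0.39 and none rose (0 and 0 adjusted over the list alone), and RPS25 had limma adjusted p = 0.102 after cyclic loess. This list, with a median of -0.07, was lower by camera (adjusted p = 0.00577), with adjusted p = 0.62 with an estimated correlation and 0.0632 without ING2 siRNA replicate 3. After cyclic loess its median was 0.05 and the camera direction higher (adjusted p = 0.358).

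In the unfolded protein response 2 of 30 genes rose and 1 fell (3 and 3 adjusted over the list alone, median -0.04, camera adjusted p = 0.468). PPP1R15A, which directs dephosphorylation of eIF2 alpha, rose by 0.40, CHAC1 rose by 0.32 (0.29 with limma adjusted p = 0.0591 after cyclic loess), and the chaperone gene HSP90B1 fell by 0.73 (SE 0.10, adjusted p = 0.0134). None of 31 hypoxia and glycolysis genes passed in limma, also adjusted over the list alone, and 4 were higher and 7 lower at an unadjusted p under 0.05. The smallest p-values were those of GPI (0.28, SE 0.08) and HK1 (0.27, SE 0.08), which had limma adjusted p = 0.0515 and 0.0634, and 0.0321 and 0.0392 after cyclic loess. The list had a median of -0.05 (camera adjusted p = 0.232). Genes of RNA interference had 0 rises and 3 falls among 12 (1 and 3 adjusted over the list alone, median -0.13). DICER1, which cuts microRNA precursors, fell by 0.57 (SE 0.09, limma adjusted p = 0.0193), its partner PRKRA fell by 0.45 and TNRC6A fell by 0.42, the last with adjusted p = 0.0595 after cyclic loess. For DICER1 and TNRC6A, 3 of 6 probe sets had a value below 0. The list did not pass (camera adjusted p = 0.0889), with adjusted p = 0.0367 without ING2 siRNA replicate 3 and 0.432 without replicate 1. Relative to the control mean, its mean was -0.23 in ING2 siRNA replicate 1 and -0.04 and -0.06 in replicates 2 and 3.

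Markers of other cells that a culture could hold gave no list past the threshold. Of 18 luminal breast markers TFF1 rose by 0.46 (2 higher and 1 lower adjusted over the list alone, median 0.00, mean 0.03, camera adjusted p = 0.934), with limma adjusted p = 0.0617 after cyclic loess. In 14 fibroblast markers 3 rose and 1 fell, also adjusted over the list alone (median 0.06, camera adjusted p = 0.533). DCN (0.35), FBLN1 (0.34) and PDPN (0.32) rose from below the median intensity and did not pass after cyclic loess (limma adjusted p = 0.0874, 0.0870 and 0.149), and LUM fell by 0.87 (SE 0.15, adjusted p = 0.0205). Of 13 blood cell markers LYZ fell by 0.51 (SE 0.14) and none rose (2 and 2 adjusted over the list alone), with a median of 0.11 and a lower camera direction (adjusted p = 0.940). Across the 27 lists, camera called 10 lower and 0 higher in the deposited values, 1 (mitosis) after quantile normalization or cyclic loess and 0 with an estimated correlation, where 0 lists had an unadjusted p under 0.05. By fry, which tests a list's own genes and not against others, 1 list passed, the ING family. That list holds the knocked-down gene ING2 itself, and fry was not run without it.

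**Figure D4:**
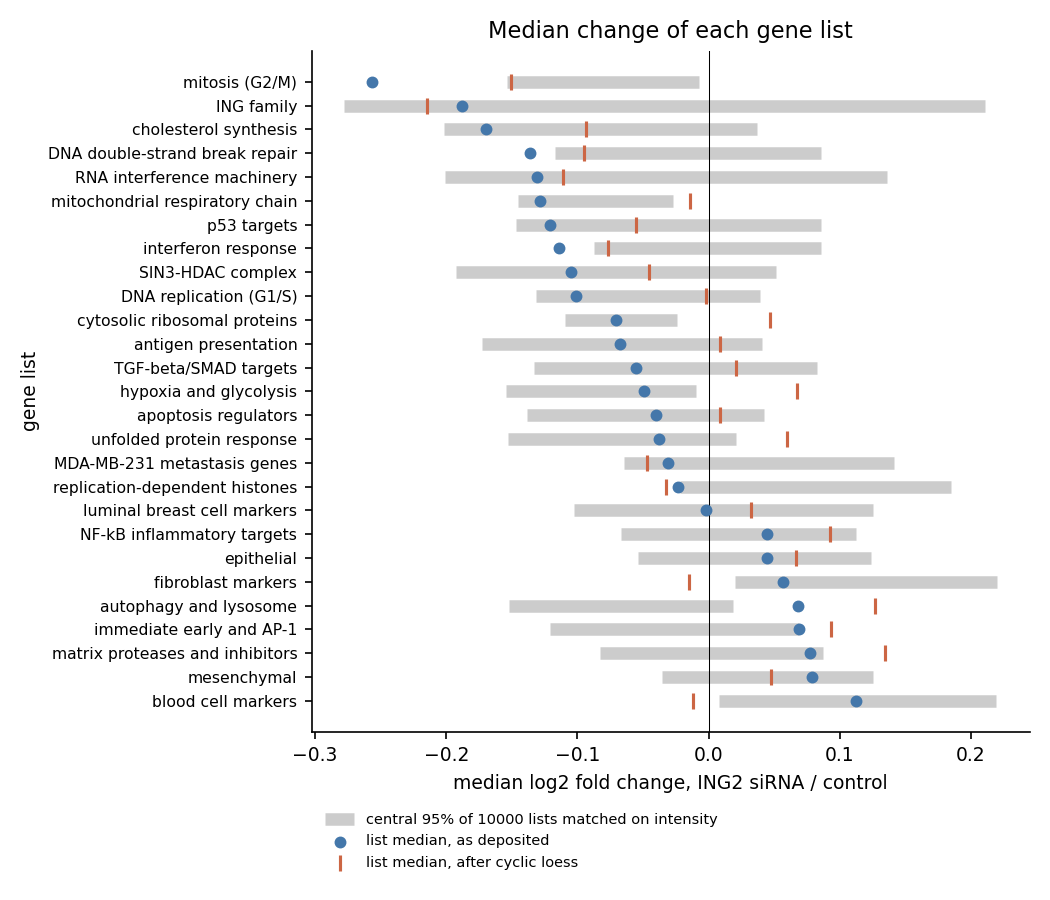
Median log2 change after ING2 siRNA (x axis) of each of the 27 gene lists (y axis), in the deposited values and after cyclic loess, with grey bars for the central 95% of random lists matched on intensity in the deposited values. The medians of the mitosis, double-strand break repair, interferon response and histone lists lie to the left of their bars, and those of autophagy and of immediate early genes to the right.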

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

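Of the tests in this part, cyclic loess and the tests of the mitosis pattern were chosen after the results were seen.

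Among probe sets with no single gene name, which the comparison of genes does not use, 283 were higher after ING2 siRNA than in the controls (limma, Benjamini-Hochberg adjusted p under 0.05), 258 with no gene listed and 25 with several. In the other direction 113 and 59 were lower. Probe set 1557856_at was higher by 0.77 on the log2 scale (SE 0.13, limma adjusted p = 0.0141), from a mean log2 intensity of 3.54 to 4.31, and the largest falls were those of 231042_s_at (-1.28, limma adjusted p = 0.0103) and 223079_s_at (-1.16, limma adjusted p = 0.00276).

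Genes that rose were mostly dim. After cyclic loess, which removes an intensity trend between the arrays, 17.2% of the 522 rises below the median intensity were still called, against 176 of 194 rises above it. Cyclic loess raised the values of the bright rises, whose median went from 0.38 to 0.43. The share kept among bright rises is therefore no control for that among dim ones. All 522 stayed above 0, which was to be foreseen, since called rises were larger than the shift by cyclic loess. In the dim bin with the largest median, that median went from 0.15 to 0.03. The median log2 change of the 522 went from 0.39 ± 0.06 to 0.29 ± 0.06 (SD over genes, median SE 0.09 in both). Calls thus ended because values near the threshold shrank in part, their median adjusted p in limma going from 0.0365 to 0.0763. The trend therefore may account for a part of these rises, and whether it was the whole cause stays open, since it goes with the groups on these arrays. Loss of repression in cells with less of a deacetylase subunit may also raise genes of low signal, and stays open as an untested hypothesis.

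Mitosis genes were lower. The intensity trend is argued against as the whole cause, because the list's median was below that of all but 0.01% of the random lists matched on intensity, and the list still passed after cyclic loess (mean per array -0.19 ± 0.03 after ING2 siRNA against ± 0.09 in controls, SD, n = 3, exact permutation p = 0.1), though not in the deposited values with an estimated correlation (adjusted p = 0.56) or by fry (adjusted p = 0.110). Fewer cycling cells may lower these genes, and would lower the DNA replication genes too, whose median lay at percentile 9.71 of matched lists, between the bounds set, so this stays open. A difference in RNA integrity between the groups also stays open, as does an effect of this siRNA on other transcripts, since 1 siRNA was used. The camera call was also given by other splits of the 6 arrays, down to adjusted p = 1.12e-07, with medians from -0.10 to 0.16. Those splits hold both groups in unequal shares, so a part of the siRNA difference stays in them. They therefore do not measure how often the call arises by chance.

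The number of genes and of lists was counted in all 10 splits of the 6 arrays into 3 and 3, which are too few for a share under 0.05. The real split gave 1640 genes and the highest other gave 0, so 1 of 10 splits gave as many. All other splits hold both groups in unequal shares. A difference between the groups widens the spread within such splits, and a part of it stays between their sides. Their counts of genes and lists therefore do not measure chance alone. For lists, the real split gave 10 and the highest other 12, so 2 of 10 gave as many. That other split set control replicates 1 and 2 and ING2 siRNA replicate 2 against the rest.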

How the results depend on the processing

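Cyclic loess and the ING family list without ING2 were chosen after the data were seen. Fitted per gene, the fall of ING2 ranged from -3.07 to -2.22 on the log2 scale over the normalizations, filter, probe set choices, variance model, weights, block and arrays left out, and passed in each. Its dimmer probe set alone gave -1.45. The numbers of genes did not keep. Against 716 higher and 924 lower (43.7% higher), centring each array on its median gave 263 and 1445 (15.4%), quantile normalization 951 and 624 (60.4%) and cyclic loess 446 and 682 (39.5%); 404 and 556 of the original calls remained after quantile normalization. The mean of all probe sets gave 2620 genes (1229 and 1391), the probe set with the largest interquartile range 3260 (1307 and 1953), array weights 3858 (1927 and 1931), an intensity trend with robust eBayes 1436 lower, and each probe set on its own 2886, 1989 of them lower. The replicate block gave 3508 genes (1630 and 1878); same-numbered arrays correlated at 0.26, 0.29 and -0.02 in their deviations, and control replicate 3 correlated best with ING2 siRNA replicate 2 (0.10), so the numbers were not taken as pairs. The block changed no list call, and 1 more named gene passed with it. An adjusted p under 0.01 left 2 genes (0 higher, 2 lower) and a log2 change of at least 1 left 5 (0 and 5). An ordinary two-sample test gave 0 genes (0 and 0; lowest adjusted p 0.0517; 4919 at an unadjusted p under 0.05). Leaving out each array gave 2 to 2613 genes (0 to 1227 higher, 2 to 1631 lower), with 1 to 24 of the 24 largest rises and falls past the threshold; 4562 to 7123 genes had an unadjusted p under 0.05. The cause of these shifts was not tested.

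Of 10 lists called, 1 stayed called after quantile normalization, 1 after cyclic loess, 2 without dim probe sets and 0 with an estimated correlation. By fry 1 stayed called, the ING family, which holds ING2 itself. With the probe set of largest interquartile range 8 stayed called, and 9 or 10 in the other settings. Up to 2 other lists passed in some of these. The mitosis list had adjusted p = 0.56 with an estimated correlation and 0.110 by fry, and passed in all other settings (7.79e-14 to 5.48e-06). The ribosomal protein list turned to higher after cyclic loess (adjusted p = 0.358), 10 lists that did not pass turned direction in at least 1 setting (adjusted p = 0.303 to 0.994), and TNRC6A had a value of 0.024 with the mean of its probe sets (adjusted p = 0.819). Of 66 named list members past the threshold, ING2 and EPCAM included, 42 passed after cyclic loess and 43 after quantile normalization. The 24 and 23 whose call ended kept their direction and at least 60.9% of their size. Signal over background was not tested, so dim probe sets are open to background.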

Other observations

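The gene groups in this part were chosen after the largest falls had been seen, and their tests leave out the genes that prompted them. Adjusted camera values are by Benjamini-Hochberg over the 3 groups tested.

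Genes of centromere and kinetochore assembly beyond those of the mitosis list were lower by camera (adjusted p = 4.25e-07), but not with an estimated correlation (adjusted p = 0.190). MIS18A, which primes centromeres for new histone CENP-A, fell by 0.91 (SE 0.13, limma adjusted p = 0.0170), and CENPK, of the constitutive centromere network, fell by 0.83 (SE 0.21). Over 27 other members, 0 rose and 4 fell (DSN1 -0.60, CENPH -0.60, CENPL -0.40 and BOD1 -0.31, the last with limma adjusted p = 0.141 after cyclic loess), 23 had a value below 0 and the median was -0.23, at percentile 0.07 of lists matched on intensity. After cyclic loess the median was -0.15 and the adjusted p was 0.000219 (7.31e-05 before adjustment). MIS18A and CENPK may therefore be part of a lower group of centromere genes, as a hypothesis found and tested on the same 6 arrays. Whether this is separate from the fall of the mitosis genes was not tested.

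SEC23A, a subunit of the COPII coat (-0.89, SE 0.14), and the vesicle SNARE gene SEC22B (-0.82, SE 0.11) fell, and the coat gene SEC24D had a value of -0.82 (SE 0.25, limma adjusted p = 0.0612). Over 45 other genes of ER-to-Golgi transport, 0 rose and 4 fell with a median of -0.10, at percentile 22.4 of matched lists, and camera gave adjusted p = 0.000316 in the deposited values and adjusted p = 0.190 with an estimated correlation. After cyclic loess the adjusted p was 0.586 (0.391 before adjustment), so whether the group was lower stays open. ACTL6A (-0.95) and YEATS4 (-0.88, SE 0.17), which both fell, are shared subunits among the NuA4, SRCAP and INO80 chromatin complexes. Over 29 other members of these complexes, 0 rose and 3 fell (MBTD1 -0.54, UCHL5 -0.46 and MEAF6 -0.41, the last 2 with limma adjusted p = 0.0540 and 0.0530 after cyclic loess), 16 had a value below 0 and the median was -0.02, at percentile 71.0 of matched lists. The NuA4 subunit ING3, which fell by 0.40, was not among the 29. The adjusted p of camera was 0.0535 in the deposited values, 0.228 with an estimated correlation and 0.980 after cyclic loess. The bound set against a fall of these complexes as a group, a median above the middle of matched lists, was met. Percentile 71.0 lies within the spread of matched lists, so the test does not exclude a small fall, and none was shown.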
